A study of Oryza sativa with 7 samples.

How the data were processed

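RNA sequencing of Oryza sativa (rice), cultivar Ilmi, was deposited as 1 table per library for 7 libraries of 4 tissues: leaf (2 libraries), root (1), young panicle (2) and seed (2). Per the labels' protocols, mRNA was purified with the Illumina TruSeq RNA kit and libraries followed Illumina's standard steps. The series design text gives paired-end sequencing on an Illumina HiSeq. The submitters' processing notes list bcl2fastq 1.8.4, TopHat2 2.0.4, Bowtie2, SAMtools 1.2, Cufflinks and HTSeq, and the genome build IRGSP-1.0, without saying which step each served. The strand setting, the read filters and the HTSeq version are not given in the sources used here.

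The deposited values are whole-number counts, not normalized. Each row is an exon bin, a stretch of a gene's annotated exons, named by a rice locus ID and a bin number. The tables hold 178317 bins of 37858 loci in the same order in every library. Of these loci, 11009 have 1 bin and 26849 have 2 or more. A further 5 rows at the end of each table name no gene, and they were left out of library totals and tests. They made up 12.2% to 15.8% of all counts in a library. A read that covers several bins can be counted in each of them, so a sum over bins exceeds the number of reads. With the strand setting unknown, reads from a locus and an antisense or overlapping partner cannot be told apart. Reads of near-identical gene copies can also be split between loci or lost.

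The files give locus IDs only, with no gene names, strands or coordinates. Of the 37858 IDs, 1 was matched in the RefSeq gene table for assembly ASM3414082v1, so no gene names are given and loci appear by ID. The 14 gene lists and the gene list tests that were fixed before the data were examined need names, and they were not run. The rule for naming loci, set before the data were examined, asked for a symbol or a description, 4 loci per direction and the 5 exon bins with the largest absolute difference in share. Without names it could not be applied as written, and it was changed after the data were examined: the name condition was dropped and the number was set to 2 per direction for loci and for bins. The other conditions were kept. For each of leaf vs panicle, leaf vs seed, panicle vs seed and leaf vs root, the changed rule takes called loci with a mean of 100 or more CPM (counts scaled to library size) in the higher tissue and no overlap between the libraries of both tissues. The 2 with the largest log2 fold change in each direction are given. Named exon bins were called bins in called loci with 200 or more counts per locus in every library of the pair and no overlap between libraries. The 2 with the largest difference in share in each direction are given, at most 1 bin per locus.

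Bin counts were summed per locus. Loci were kept by edgeR's filterByExpr with its minimum count of 10; because root has 1 library, 1 library over the minimum was enough, and 26784 loci were kept. Levels were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, estimateDisp, then glmQLFit and glmQLFTest in 1 model of all 7 libraries with 4 tissue means and 3 residual degrees of freedom. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold change of 2 or more. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the quasi-likelihood F. A locus was called highest in a tissue if it passed against each of the other 3 tissues. CPM values use the TMM-scaled library size unless stated otherwise. Root has 1 library, so its own spread was not measured, and its tests assume that it varies like the other tissues. Where the lower tissue had a count of 0, the fold is a bound computed against 3 counts over all libraries of that tissue. Such a bound falls by construction when a library of that tissue is left out, since 3 counts then weigh on fewer reads. Folds and bounds were recomputed without each library of the pair, with the scaling factors kept. A read can be counted in several bins, so 3 counts may come from 1 read. For loci of several bins the bounds and the counting intervals make no allowance for this.

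Exon usage was tested with edgeR's diffSpliceDGE on the bins kept by the same filter, in loci with 2 or more kept bins (117658 bins of 18512 loci). This compares each bin's log2 fold change with that of its locus. Loci were called at a Benjamini-Hochberg adjusted Simes p under 0.05, and bins within them at an adjusted bin p under 0.05. The share of a locus's counts that fell in a bin is given in percent. For the single root library the share has a 95% Wilson interval, which covers counting error only. A change in a bin's share can come from splicing, or from another start or end of the transcript; bin counts hold no junction reads.

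Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no low-count filter, the largest bin count of a locus in place of the sum, only the libraries of both tissues in the fit, no fold minimum, a 4-fold minimum for loci highest in a tissue, the replicate number as a block, and leaving out each library in turn (root 1 only in the pairs without root, and not for loci highest in a tissue). For exon usage they were the gene-level F test, voom with diffSplice in limma 3.58.1, a mean of 20 or more counts per bin, a fold minimum for the leading bin, the block and leaving out each library in turn, with the same limit for root 1. These alternatives, the tests and the thresholds were chosen before the data were examined. Thinning all libraries to 11989260 counts and leaving out the 100 most abundant loci were added after seeing the data. Fits on other libraries or other counts ran the filter anew, so they need not cover the same loci.

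The tests were tested on simulated data with the real library sizes and 1 mean per feature taken over all libraries. In these, 200 features were changed between leaf and panicle. The simulated tissues did not differ otherwise, and all had the same trended dispersion. Exon usage was simulated in loci with 3 or more kept bins. The rates below hold for that setting and were not measured for tissues that differ at many loci or in spread. Over 26784 simulated loci, the level test recovered 35 of 100 loci changed 4-fold and 64 of 100 changed 8-fold, with 6 false calls. Over 14638 simulated loci for exon usage, 7 of 100 loci with 1 bin changed 4-fold and 61 of 100 changed 8-fold were recovered, with 3 false calls. Library totals ran from 11989260 to 49312943 counts, so 3 counts correspond to between 0.0608 and 0.250 CPM before scaling.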

Results

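Transcript levels and exon usage were measured by RNA sequencing in 4 tissues of the rice cultivar Ilmi. Leaf and root were taken at 14 days, flowers before pollination from panicles of 0.5 to 1.5 cm, and seed at 20 to 30 days after pollination (the sample names give 21). Leaf, panicle and seed had 2 libraries each, and root had 1. Counts over exon bins came to 22218323 and 49312943 in leaf, 20940842 in root, 19717360 and 16139784 in panicle, and 17866682 and 11989260 in seed. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical. The series title gives the question as which genes have alternatively spliced transcripts in these tissues.

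A few loci took a large part of the bin counts in seed and leaf, and the counts in panicle were the most even of the 4 tissues. A read over several bins counts in each, so these are not shares of reads or of transcripts. Loci of many bins can weigh more than loci of few. The locus Os01g0762500 alone held 4.17% and 8.63% of counts in the 2 seed libraries. In leaf, Os11g0707000 held 3.24% and 3.37%. The most abundant locus held 0.890% in root and, in panicle, 0.721% and 0.738%. The 10 most abundant loci together took 16.2% and 26.9% in seed, 8.16% and 9.38% in leaf, 4.14% in root, and 3.26% and 3.81% in panicle. These 2 loci are the most abundant of their tissues and were singled out after their values were seen. Loci at 1 CPM or more, here without TMM scaling, were similar in number in all libraries, from 18937 in leaf 1 to 19788 in panicle 1. The TMM factors ran from 0.781 in leaf 2 to 1.51 in panicle 1, so the numbers and their order could differ after scaling.

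**Figure D1:**
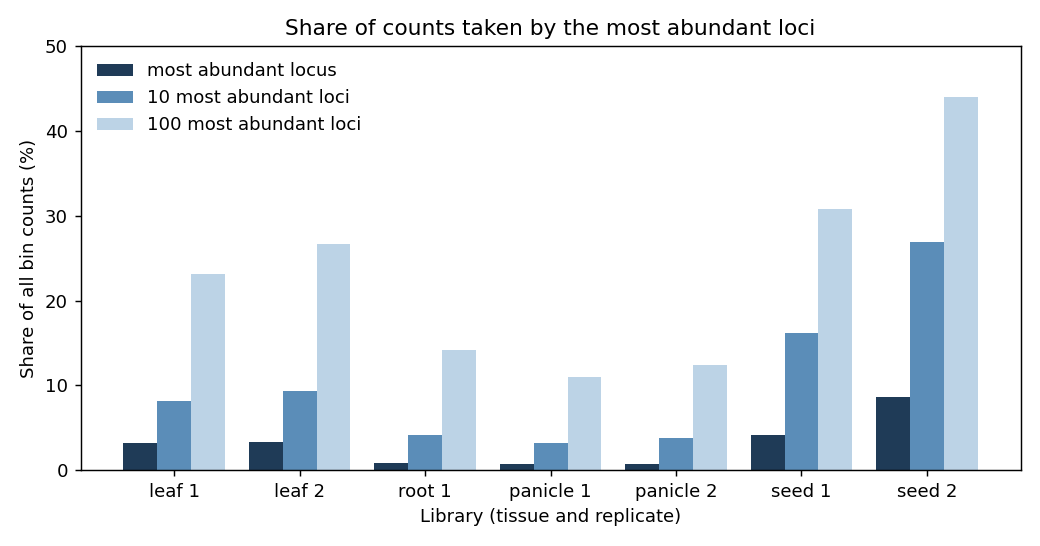
Share of all bin counts (%, vertical axis) taken by the most abundant locus, the 10 most abundant and the 100 most abundant loci in each of the 7 libraries. The 100 most abundant loci took 30.8% and 43.9% in seed and at most 12.4% in panicle.

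Libraries of 1 tissue resembled each other more than those of different tissues. Across loci, which are not independent replicates, log2 CPM correlated at r = 0.978 between the leaf libraries, 0.962 between the panicle libraries and 0.910 between the seed libraries. Between libraries of different tissues r ran from 0.652 to 0.761. The seed libraries stood further apart than the other replicate pairs, with a median absolute log2 difference of 0.66 per locus, against 0.37 in leaf and 0.32 in panicle.

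Each tissue had a set of loci that it expressed at a higher level than each of the other 3. There were 1672 such loci in leaf, 1175 in root, 639 in panicle and 801 in seed, of 26784 tested (edgeR, adjusted p under 0.05 and 2-fold or more against every other tissue). The 1672 leaf loci held 37.9% and 42.3% of counts in the leaf libraries and between 2.01% and 3.56% in the others. The 801 seed loci held 31.3% and 47.2% of counts in seed and between 0.784% and 1.26% elsewhere. The 1175 root loci held 17.2% of counts in root and between 1.48% and 1.72% elsewhere. The 639 panicle loci held 5.59% and 6.31% in panicle and between 0.483% and 0.855% elsewhere. Because these sets were chosen on the same libraries, the shares describe their size and are not independent evidence. The median excess over the next highest tissue, on the log2(CPM + 0.5) scale, was 3.50 in seed, 3.25 in root, 2.88 in leaf and 1.88 in panicle.

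Loci of a single exon bin were less frequent among the leaf loci, at 15.8% against 21.9% of the other tested loci (Fisher's exact test, two-sided, adjusted p = 5.24e-09 over 4 tissues). The panicle loci also had fewer, at 15.5% against 21.7% (adjusted p = 0.000232). In root (20.1% against 21.6%, adjusted p = 0.231) and seed (18.7% against 21.6%, adjusted p = 0.0728) the difference went the same way but did not pass. The groups were not matched on counts. Counts are summed over bins, so loci of 1 bin may have less power to be called in any tissue, which was not tested. The loci of each tissue were spread over the 12 chromosomes, as read from the locus IDs. None of 48 Fisher's exact tests of 1 tissue on 1 chromosome passed after adjustment, and the smallest adjusted p was 0.103. The counts of loci moved with single libraries. Those for leaf were 907 without leaf 1 and 753 without leaf 2. Those for root were 396 without leaf 1 and 351 without leaf 2. Those for seed were 409 and 384 without the same libraries. Those for panicle were 133, 175, 324, 185, 1128 and 1033 without leaf 1, leaf 2, panicle 1, panicle 2, seed 1 and seed 2, 1018 with DESeq2 and 327 at a 4-fold minimum.

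Leaf and young panicle differed in level at 8040 of 26784 loci (30.0%), of which 5696 were higher in leaf and 2344 higher in panicle. Changes over 8-fold were also more frequent towards leaf, with 3520 loci against 580. Os08g0139700 had 1076 ± 76.0 CPM (SD, n = 2) in leaf and no count in either panicle library, which makes it at least 19018-fold higher in leaf (edgeR, adjusted p = 0.000391). Os01g0823600 had 911 ± 277 CPM (SD, n = 2) in leaf and no count in panicle, at least 16101-fold higher (edgeR, adjusted p = 0.000369). In the other direction, Os07g0108900 had 383 ± 82.0 CPM (SD, n = 2) in panicle and no count in leaf, at least 7157-fold higher in panicle (edgeR, adjusted p = 0.000369). This locus also had 106 ± 2.11 CPM (SD, n = 2) in seed and 0.185 CPM in root. Os06g0162800 had 127 ± 62.3 CPM (SD, n = 2) in panicle and 1 count in leaf, a ratio of 7097 with a 95% counting interval of 1274 to 280315 (edgeR, adjusted p = 0.000372). That count is in leaf 2, without which it was at least 740-fold higher, and without panicle 1 the ratio was 4629. The bounds against panicle were 0.437 and 0.563 times as large without panicle 1 and panicle 2, and that against leaf 0.313 times without leaf 2. With the largest bin count of each locus in place of the sum, all these log2 fold changes were smaller. With no count or 1 count in the lower tissue this largely follows by construction, since mainly the higher tissue's count shrinks. Where the lower tissue had no count, the log2 fold change rests on a small count that edgeR adds. Such a value is not a measured fold. The log2 fold change was 15.5 for Os08g0139700 (17.6 with the sum) and 16.1 for Os01g0823600 (17.3). It was -13.5 for Os07g0108900 (-16.1) and -10.2 for Os06g0162800 (-12.4).

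The split between leaf and panicle moved in both directions with the libraries and loci used. The share of called loci that were higher in leaf was 70.8%. It was 90.4% (3297 against 350) without leaf 1 and 88.4% (3076 against 405) without leaf 2, but 60.1% (5120 against 3395) without the 100 most abundant loci and 59.7% (6221 against 4203) with only the leaf and panicle libraries in the fit. With RLE in place of TMM factors, and nothing else changed, it was 67.2%. The TMM factors were 0.789 and 0.781 in leaf and 1.51 and 1.44 in panicle. Leaving out the abundant loci moved the median log2 fold change of all loci from 0.08 to -0.07. Counts were 3647 without leaf 1, 3481 without leaf 2, 4335 without panicle 1 and 4401 without panicle 2.

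**Figure D2:**
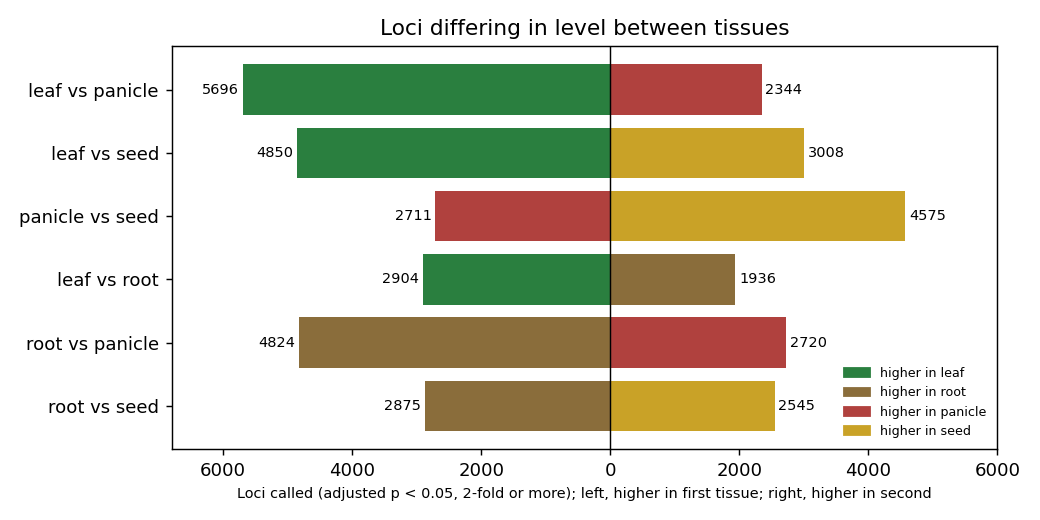
Number of loci called in each of the 6 tissue pairs (horizontal axis), with bars to the left for loci higher in the first tissue of the pair and to the right for loci higher in the second. Leaf vs panicle had 5696 and 2344, and panicle vs seed 2711 and 4575.

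Exon usage differed between leaf and panicle in 42 of 18512 loci. In these loci 58 bins were called, of which 38 took a larger share of their locus in leaf and 20 in panicle. Bin 1 of 3 of Os03g0816500 held 54.6% ± 3.44 (SD, n = 2) of the locus's counts in leaf and 7.87% ± 3.02 (SD, n = 2) in panicle (edgeR, adjusted p = 0.0129). The level of this locus was not called, with a log2 fold change of 0.14 (edgeR, adjusted p = 0.812). Bin 24, the last of Os02g0280400, held 45.5% ± 21.1 (SD, n = 2) in leaf and 1.96% ± 0.714 (SD, n = 2) in panicle (edgeR, adjusted p = 1.07e-11). Its 2 leaf libraries were far apart, at 30.6% and 60.5%, and both lay above every library of the other tissues. Bin 11 of 13 of Os04g0573200 went the other way, with 8.54% ± 3.90 (SD, n = 2) in leaf and 35.8% ± 5.66 (SD, n = 2) in panicle (edgeR, adjusted p = 0.0179). Bin 3 of 6 of Os07g0619200 held 6.16% ± 2.65 (SD, n = 2) in leaf and 30.0% ± 2.72 (SD, n = 2) in panicle (edgeR, adjusted p = 0.0179). Apart from that of Os02g0280400, these calls were lost without any 1 of the 4 libraries of the pair, while the changes stayed in the same direction. Their log2 change in usage then ran from 2.45 to 3.25 for Os03g0816500 (2.82 with all libraries), -2.63 to -1.66 for Os04g0573200 (-2.04) and -2.81 to -1.90 for Os07g0619200 (-2.30). Without leaf 1, leaf 2, panicle 1 and panicle 2 in turn, the edgeR adjusted p was 0.541, 0.203, 0.95 and 0.468 for Os03g0816500, 1, 0.135, 0.971 and 0.362 for Os04g0573200, and 0.399, 1, 0.625 and 0.384 for Os07g0619200. The last of these was not called with voom and diffSplice (adjusted p = 0.206) or at a mean of 20 or more counts per bin (edgeR, adjusted p = 0.128). The lowest adjusted p over all alternatives was 0.000873, 0.000186 and 0.00285 for the same loci, and for Os02g0280400 the range was 9.52e-16 to 0.00281. Its log2 change in usage was 4.61, and 3.92 without leaf 2.

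Of the 42 loci with a difference in usage, 29 were also called for level, against 14.3 for independent lists (Fisher's exact test, two-sided, adjusted p = 2.5e-05 over 6 pairs). A locus's level is the sum of the same bins, so a shifted bin also moves the level. The lists are therefore not independent, here or in the other pairs. These tests cannot separate a link between usage and level from the shared counts. First and last bins made up 37.9% of called bins and 28.1% of tested bins, which did not pass (Fisher's exact test, adjusted p = 0.177). That test took bins of the same locus as independent and was not matched on the number of bins per locus. Only 7, 8, 10 and 6 loci were called for usage without leaf 1, leaf 2, panicle 1 and panicle 2, and 66 without seed 1. Voom with diffSplice called 69.

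Leaf and seed differed in level at 7858 loci (29.3%), of which 4850 were higher in leaf and 3008 higher in seed. Os07g0206500, a locus of 1 bin, had 10878 ± 5514 CPM (SD, n = 2) in seed and no count in leaf, at least 203210-fold higher (edgeR, adjusted p = 0.00109). Os12g0269600 had 9521 ± 3376 CPM (SD, n = 2) in seed and no count in leaf, at least 177867-fold higher (edgeR, adjusted p = 0.000961). Both had between 0.0647 and 0.648 CPM in panicle and root. Os03g0658800 had 417 ± 14.9 CPM (SD, n = 2) in leaf and no count in seed, at least 3585-fold higher in leaf (edgeR, adjusted p = 0.000927). Os03g0843800 had 298 ± 29.8 CPM (SD, n = 2) in leaf and no count in any library of the other 3 tissues, at least 2567-fold higher than in seed (edgeR, adjusted p = 0.000928). The bound for Os07g0206500 was 130366-fold without seed 2. Bounds against leaf were 0.313 times as large without leaf 2, and those against seed 0.367 and 0.633 times without seed 1 and seed 2. The share of called loci higher in leaf was 61.7%, but 75.4% of 3117 (2351 against 766) without leaf 1 and 72.9% of 2429 (1770 against 659) without leaf 2. The median log2 fold change of all kept loci was 0.08, and -0.03 with only these tissues in the fit. The filter was run anew there, so the medians need not cover the same loci.

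Exon usage differed between leaf and seed in 29 of 18512 loci, with 28 bins of larger share in leaf and 15 in seed. The last of the 15 bins of Os08g0345800 held 34.4% ± 1.52 (SD, n = 2) of the locus's counts in seed and 0.459% ± 0.163 (SD, n = 2) in leaf (edgeR, adjusted p = 0.000394). The locus itself was also higher in seed, with a log2 fold change of leaf over seed of -3.14 (edgeR, adjusted p = 0.00227). Bin 1 of 5 of Os01g0197400 held 28.1% ± 0.135 (SD, n = 2) in seed and 3.14% ± 0.851 (SD, n = 2) in leaf (edgeR, adjusted p = 0.0389). Towards leaf, bin 24 of Os02g0280400 held 45.5% ± 21.1 (SD, n = 2) in leaf and 4.71% ± 1.21 (SD, n = 2) in seed (edgeR, adjusted p = 1.05e-06). Bin 3 of 12 of Os04g0619200 held 32.2% ± 3.51 (SD, n = 2) in leaf and 3.37% ± 1.56 (SD, n = 2) in seed (edgeR, adjusted p = 0.000791). Of the 29 loci, 20 were also called for level, against 9.53 for independent lists (Fisher's exact test, adjusted p = 0.00025). The bin of Os08g0345800 was not called without leaf 1 (edgeR, adjusted p = 0.0575) or leaf 2 (0.126), and that of Os04g0619200 not without leaf 2 (0.132). Their log2 changes in usage, -6.30 and 3.23, were then -6.64, -5.90 and 3.12. For Os02g0280400 the change was 3.40, and 2.70 without leaf 2. The bin of Os01g0197400 was not called with voom and diffSplice (adjusted p = 0.072), nor with edgeR without leaf 2, panicle 1, panicle 2, seed 1 or seed 2 (adjusted p = 0.4, 0.27, 0.268, 0.206 and 0.205), and its lowest over all alternatives was 0.0221. Its log2 change in usage was -3.23 and ran from -3.46 to -2.89 with 1 library left out. Usage calls fell to 8 without leaf 1 and to 8 without leaf 2, and were 16, 18 and 16 without panicle 1, panicle 2 and seed 1. Both the F test and voom with diffSplice called 44.

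**Figure D3:**
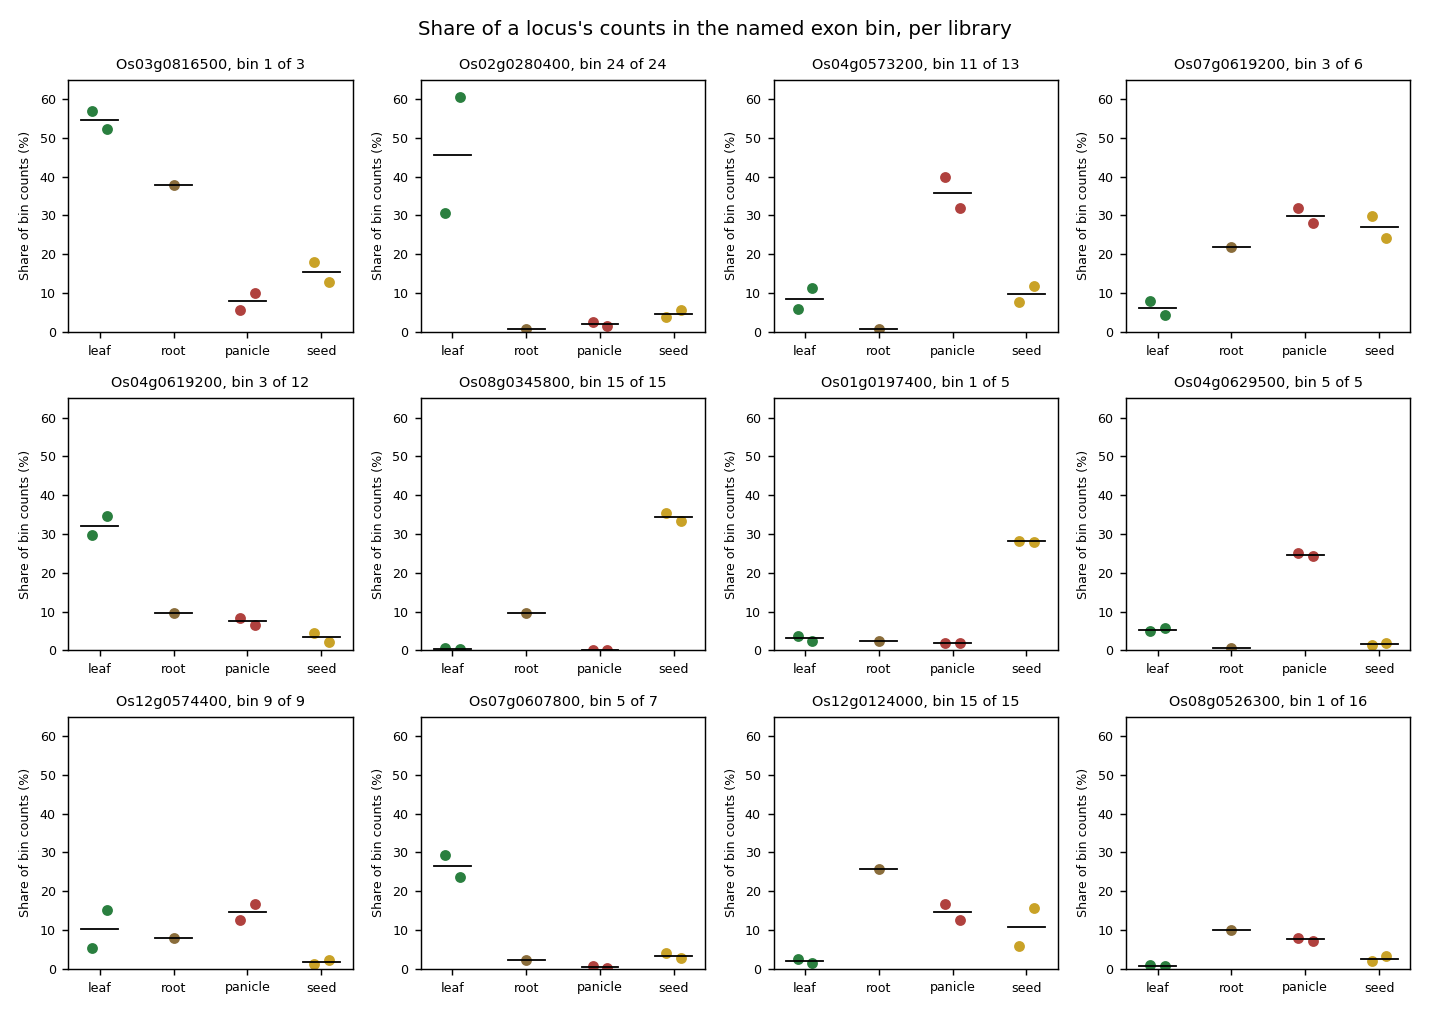
Share of a locus's bin counts that fell in 1 exon bin (%, vertical axis) in each library of the 4 tissues, for the 12 exon bins named in the text. Each point is a library and each line a tissue mean; root has 1 library. The last bin of Os08g0345800 stands at 35.5% and 33.4% in the seed libraries, 9.72% in root and below 1% in leaf and panicle.

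Panicle and seed differed in level at 7286 loci (27.2%), of which 2711 were higher in panicle and 4575 higher in seed. Os02g0249000 had 5823 ± 4620 CPM (SD, n = 2) in seed and no count in panicle, at least 102955-fold higher (edgeR, adjusted p = 0.00235). Os12g0269200 had 4040 ± 4841 CPM (SD, n = 2) in seed and no count in panicle, at least 71426-fold higher (edgeR, adjusted p = 0.00376). The seed libraries differed widely at this locus, with 10069 counts in seed 1 and 70719 in seed 2. Its bound was 131948-fold without seed 1 and 10904-fold without seed 2, and that of Os02g0249000 was 160706-fold and 45204-fold. The bounds against panicle were 0.437 and 0.563 times as large without panicle 1 and panicle 2. Towards panicle, Os02g0662100 had 106 ± 36.7 CPM (SD, n = 2) in panicle and 2 counts in seed, a ratio of 1368 with a 95% counting interval of 379 to 11292 (edgeR, adjusted p = 0.00152). Both counts are in seed 2. Without seed 2 the locus was at least 577-fold higher, and without seed 1 the ratio was 502. This locus also had 149 ± 87.1 CPM (SD, n = 2) in leaf. Os04g0536300 had 183 ± 59.8 CPM (SD, n = 2) in panicle and 0.906 ± 1.11 CPM (SD, n = 2) in seed, a log2 fold change of 7.82 (edgeR, SE 0.98, adjusted p = 0.00286). It had 2 counts in seed 1 and 16 in seed 2, and the log2 fold change was 6.75 without seed 1 and 10.48 without seed 2. Counts were 3817 without panicle 1 and 3551 without panicle 2. The median log2 fold change of all kept loci was -0.10, and 0.00 with only these tissues in the fit. The filter was run anew there, so the medians need not cover the same loci.

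Exon usage differed between panicle and seed in 21 of 18512 loci, with 10 bins of larger share in panicle and 23 in seed. The last bin of Os08g0345800 again differed, from 0.0485% ± 0.0687 (SD, n = 2) in panicle to 34.4% ± 1.52 (SD, n = 2) in seed (edgeR, adjusted p = 9.5e-05). Bin 14 of this locus was called the other way, towards panicle (edgeR, log2 change in usage 5.55, adjusted p = 0.000134). Bin 1 of Os01g0197400 held 1.81% ± 0.0196 (SD, n = 2) in panicle and 28.1% ± 0.135 (SD, n = 2) in seed (edgeR, adjusted p = 0.00808). The last of the 5 bins of Os04g0629500 held 24.6% ± 0.503 (SD, n = 2) in panicle and 1.61% ± 0.279 (SD, n = 2) in seed (edgeR, adjusted p = 4.97e-06), while the level of the locus was not called (log2 fold change -0.34, adjusted p = 0.452). The last of the 9 bins of Os12g0574400 held 14.6% ± 2.92 (SD, n = 2) in panicle and 1.78% ± 0.578 (SD, n = 2) in seed (edgeR, adjusted p = 0.002). Of the 21 loci, 13 were also called for level, against 6.30 for independent lists (Fisher's exact test, adjusted p = 0.00469). The bin of Os08g0345800 was not called without panicle 1 (edgeR, adjusted p = 0.085) or panicle 2 (0.342), that of Os12g0574400 not without panicle 2 (0.508) or seed 1 (0.108), and that of Os01g0197400 not without panicle 1, panicle 2, seed 1 or seed 2 (0.981, 1, 0.0716 and 0.0501). The log2 change in usage of Os08g0345800 was -9.08, and -11.39 without panicle 1 and -8.28 without panicle 2. That of Os12g0574400 was 3.07 and ran from 2.76 to 3.43 with 1 library left out, and that of Os01g0197400 was -3.95 and ran from -3.96 to -3.93. The bin of Os04g0629500 was called in every alternative run, with an adjusted p of at most 0.00673. Usage calls were 10 without panicle 1, 6 without panicle 2, 51 without seed 2 and 36 by the F test.

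Leaf and root were compared at the same age, with 1 root library. In level 4840 loci (18.1%) were called, of which 2904 were higher in leaf and 1936 higher in root. Os09g0564400 had 372 CPM in root and no count in any library of the other tissues, at least 6948-fold higher than in leaf (edgeR, adjusted p = 0.00184). Os10g0335000 had 285 CPM in root and no count in leaf, at least 5316-fold higher (edgeR, adjusted p = 0.00113). Towards leaf, Os08g0139700 was at least 7750-fold higher than in root, where it had no count (edgeR, adjusted p = 0.00151). Os08g0460000, a locus of 1 bin, had 656 ± 290 CPM (SD, n = 2) in leaf and no count in root, at least 4728-fold higher (edgeR, adjusted p = 0.00342). The bounds against leaf were 0.313 times as large without leaf 2. The share of called loci higher in leaf, 60%, was 75.9% (1577 against 500) without leaf 1 and 75.6% (1329 against 428) without leaf 2. Counts were 2077 without leaf 1, 1757 without leaf 2, 7359 without seed 1, 7356 without seed 2, and 9488 with only the leaf and root libraries in the fit.

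Exon usage differed between leaf and root in 14 of 18512 loci, with 15 bins of larger share in leaf and 4 in root. Bin 24 of Os02g0280400 held 45.5% ± 21.1 (SD, n = 2) in leaf and 0.657% in root (95% Wilson interval 0.358% to 1.21%; edgeR, adjusted p = 5.37e-09). Bin 5 of 7 of Os07g0607800 held 26.5% ± 4.04 (SD, n = 2) in leaf and 2.26% in root (1.61% to 3.15%; edgeR, adjusted p = 0.00639). The last of the 15 bins of Os12g0124000 held 25.7% in root (21.3% to 30.5%) and 1.99% ± 0.645 (SD, n = 2) in leaf (edgeR, adjusted p = 4.52e-07). Bin 1 of 16 of Os08g0526300 held 9.97% in root (7.82% to 12.6%) and 0.843% ± 0.0576 (SD, n = 2) in leaf (edgeR, adjusted p = 0.000159). These 2 loci were higher in leaf than in root, by 5.49 and 4.12 on the log2 scale. First and last bins made up 63.2% of called bins (12 of 19) against 28.1% of tested bins (Fisher's exact test, adjusted p = 0.009), the only one of the 6 pairs in which this passed. The test took bins as independent, but the 19 bins lie in 14 loci and some loci have several called bins. It was also not matched on the number of bins per locus. The p-value therefore cannot settle whether end bins were favoured. Of the 14 loci, 7 were also called for level, against 2.92 for independent lists (Fisher's exact test, adjusted p = 0.0174). The bin of Os07g0607800 was not called without leaf 1, leaf 2, panicle 1 or panicle 2 (edgeR, adjusted p = 0.141, 0.144, 0.0552 and 0.0551), that of Os08g0526300 not without leaf 1 or leaf 2 (0.135 and 0.22), and that of Os12g0124000 not without leaf 2 (0.145). With 1 library left out their log2 changes in usage ran from 3.39 to 3.70, from -3.64 to -3.50 and from -4.08 to -3.41. For Os02g0280400 the change was 6.22, and 5.52 without leaf 2. Usage calls were 3, 3, 9, 8, 28 and 26 without leaf 1, leaf 2, panicle 1, panicle 2, seed 1 and seed 2, 29 by the F test and 36 with voom and diffSplice.

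Root differed from panicle in level at 7544 loci, of which 4824 were higher in root and 2720 higher in panicle. Against seed, 5420 loci were called, with 2875 higher in root and 2545 higher in seed. The majority in root vs seed was not stable. It turned with DESeq2 (3713 higher in root and 3761 higher in seed), with the largest bin count of each locus (2673 and 2721), and without panicle 1 (2204 and 2269), panicle 2 (2246 and 2322) or seed 2 (3471 and 3506). In root vs panicle the median log2 fold change of all loci moved from -0.05 to -0.17 without the 100 most abundant loci. Exon usage differed in 23 loci between root and panicle and in 8 between root and seed. Of the 23 loci, 10 were also called for level, against 7.31 for independent lists, and the difference did not pass (Fisher's exact test, adjusted p = 0.263). Of the 8, 6 were, against 1.89 (adjusted p = 0.00469). Level calls for root vs panicle were 5025, 4111 and 4376 without leaf 1, panicle 1 and panicle 2, and for root vs seed 2990 and 3012 without leaf 1 and leaf 2, and 2117 with only these tissues in the fit. Usage calls for root vs panicle were 9, 8, 4, 45 and 49 without leaf 1, panicle 1, panicle 2, seed 1 and seed 2, and for root vs seed 5 and 4 without leaf 1 and panicle 2. The F test called 75 and 44 for the same pairs, and voom with diffSplice 74 and 26.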

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

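Each table ends with counts that belong to no single exon bin and enter no comparison, and they were singled out because they hold reads. Reads outside annotated exons made up 3.34% and 3.43% of counts in the leaf libraries, 3.96% in root, 6.16% and 4.70% in panicle, and 3.27% and 3.99% in seed. Both panicle libraries lay above the other 5. Reads over several genes made up 10.3% and 12.1% in leaf, 11.4% in root, 9.58% and 10.3% in panicle, and 8.44% and 8.50% in seed. Read pairs of unclear position made up 0.364% and 0.194% in leaf, 0.368% in root, 0.0266% and 0.207% in panicle, and 0.443% and 0.215% in seed. Panicle 1 had the lowest share of such pairs and the highest share of reads outside exons. The total behind these percentages is the bin counts plus these rows. A read over several bins adds to that total more than once, so they are not shares of reads. Differences between tissues can also depend on how many bins a read covers. No test was run on these shares.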

How the results depend on the processing

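All alternatives named here were chosen before the data were examined, except thinning and leaving out abundant loci. None of the 16 named changes in level lost its call or its direction in any fit that gave a value (232 fits), and none of the 16 named changes in bin usage changed direction (156 fits), though 38 of these fits lost the call, all but 3 with a library left out. The named loci and bins were chosen on these same libraries as called, with the largest changes and no overlap between libraries. Their keeping of call and direction was therefore largely set by that choice and says little about other loci. Counts of loci differing in level stayed within 1.5 times with DESeq2, RLE factors, no filter, the largest bin count, no fold minimum, thinning and without the 100 most abundant loci. With only the libraries of both tissues the count was 9488 for leaf vs root and 2117 for root vs seed, which leave 1 residual degree of freedom; the cause was not tested. Loci highest in panicle numbered 1018 with DESeq2 and 327 at a 4-fold minimum, which can only remove loci. For exon usage the gene-level F test called 44 loci in leaf vs seed, 36 in panicle vs seed, 29 in leaf vs root, 75 in root vs panicle and 44 in root vs seed, and voom with diffSplice called 69 in leaf vs panicle, 44 in leaf vs seed, 36 in leaf vs root, 74 in root vs panicle and 26 in root vs seed; the cause was not tested. In the order leaf vs panicle, leaf vs seed, panicle vs seed, leaf vs root, root vs panicle and root vs seed, 34 of 42, 25 of 29, 19 of 21, 10 of 14, 18 of 23 and 4 of 8 loci were also called by voom, and 30, 21, 19, 13, 19 and 8 by the F test.

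Leaving out a leaf, panicle or seed library leaves that tissue with 1 library, which is assumed to vary like the others. The replicate pairs did not vary alike, with median absolute log2 differences of 0.66 in seed, 0.37 in leaf and 0.32 in panicle. The model fits 1 spread per locus to all tissues. Root 1 was left out only for the 3 pairs without root, where counts stayed within 1.5 times. With 1 library left out, level calls ran from 3481 to 10386 in leaf vs panicle, 2429 to 8894 in leaf vs seed, 3551 to 8346 in panicle vs seed, 1757 to 7359 in leaf vs root, 4111 to 10705 in root vs panicle and 2990 to 7613 in root vs seed. Loci highest in a tissue ran from 753 to 2135 in leaf, 351 to 1657 in root, 133 to 1128 in panicle and 384 to 1182 in seed. Usage calls ran from 6 to 66 in leaf vs panicle, 8 to 31 in leaf vs seed, 6 to 51 in panicle vs seed, 3 to 28 in leaf vs root, 4 to 49 in root vs panicle and 4 to 12 in root vs seed. The highest counts came with a seed library left out, except for usage in leaf vs seed, where it came without root 1 (25 of the 31 loci were among the 29 called with all libraries; without seed 1, 9 of 16 were). Leaving out joined gene IDs was not run because the tables hold 0 of them.

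The replicate numbers were checked for pairing. Deviations of same-numbered libraries correlated at 0.11 for leaf and panicle, 0.21 for leaf and seed and 0.05 for panicle and seed. All 3 correlations are small and positive, which neither shows a pairing nor excludes a shared batch. The main fit did not treat the libraries as paired. With the replicate block, level calls were 8739 in leaf vs panicle, 8461 in leaf vs seed, 7933 in panicle vs seed, 4888 in leaf vs root, 7630 in root vs panicle and 5656 in root vs seed. Usage calls with the block were 53, 33, 31, 13, 24 and 12 in the same order, and loci highest in leaf, root, panicle and seed 1760, 1146, 734 and 893. In the simulation of exon usage in leaf vs panicle at these depths, 7 of 100 bins changed 4-fold and 61 of 100 changed 8-fold were recovered. The simulated tissues did not differ otherwise.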

Other observations

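The tests of depth, of scaling without abundant loci, of bins whose share moved against the level of their locus and of adjacent pairs were chosen after the data were seen. Loci that were highest in the same tissue lay next to each other more often than chance. Among tested loci in the order of their IDs along each chromosome, 440 adjacent pairs were highest in the same tissue, against a mean of 196 and a highest value of 248 in 10000 shuffles of loci within chromosomes (permutation p = 0.0001, the smallest these shuffles can give). The excess was seen in every tissue: 197 pairs against a mean of 105 in leaf, 136 against 52.6 in root, 35 against 15.3 in panicle and 72 against 23.9 in seed. Runs of 3 or more such loci numbered 29 in leaf, 22 in root, 6 in panicle and 12 in seed. The longest, singled out after its values were seen, was a root run of 6 tested loci from Os07g0538350 to Os07g0539300 on chromosome 7. In seed the longest was a run of 5 from Os07g0213600 to Os07g0214600 on the same chromosome.

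One technical account of these neighbours is that a gene was split into adjacent models or that models overlap. A gene split into 2 adjacent models, or 2 adjacent models that overlap, would leave no excess further away. Pairs 2 to 5 tested loci apart numbered 1035, above every shuffle (highest 891), so such cases cannot be the whole cause. Genes split into more models, or models lying between the parts of another, could give such pairs. Without coordinates or strands these cases stay open. Reads shared between near-identical copies in tandem remain open, since the sequences were not used here. No biological explanation of the excess was tested.

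More called loci were higher in leaf than in panicle. Unequal depth is argued against: with all libraries thinned to the smallest total, 72.6% of called loci were still higher in leaf. A distortion of the scaling by abundant transcripts stays open in part. Without the 100 most abundant loci the share was 60.1% (95% exact interval 59.1% to 61.2%), down from 70.8%, so abundant loci may account for part of the excess. The share was 90.4% and 88.4% without leaf 1 and leaf 2, so it also moves with the libraries used. A difference between the tissues themselves was not tested, because no spike-in or total RNA measure was used here.

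Loci called for exon usage between leaf and panicle were often called for level too, 29 of 42. Higher counts alone are argued against, because draws of loci matched on mean CPM gave between 8 and 20 in the central 95%. That CPM was without TMM scaling. The test had been set out with matching on gene counts, and such draws, run after the first were seen, gave between 10 and 22. Neither set of draws was matched on spread or number of bins, and the level sums the same bins. Other differences in power and this shared counting therefore stay open. A second transcript that covers the bin and does not follow its locus would make the leading bin's share move against the level of the locus. The bin's log2 fold change relative to that of its locus had the opposite sign to the level in 58.6% of the 29 loci. Bins that changed in the same direction as their locus, but less, are counted here too. The 95% exact interval, 38.9% to 76.5%, includes an even split, so this explanation stays open. That verdict depends on a criterion set with the value known: an earlier one, also set after the result, asked for 80% or more and would have counted against it. Whether start, end and splice choice shift together with level in these tissues was not tested.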
